A study of Mus musculus with 32 samples.

How the data were processed

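DNA methylation was measured by reduced representation bisulfite sequencing (RRBS) in the gastrocnemius, the large calf muscle, of mice with a complete spinal cord injury (SCI) or a sham operation. In RRBS the genome is digested at CpG-containing restriction sites and short fragments are kept, so that CpG-rich parts of the genome are read deeply. Bisulfite turns unmethylated cytosines into a base read as thymine, while methylated cytosines are read as cytosine. Per the labels, DNA came from a piece of the left muscle holding both of its heads, and a sequencing company carried out conversion, library preparation and sequencing. There were 32 libraries in 6 groups, which were sham with vehicle, SCI with vehicle and SCI with boldine, at 7 and 28 days. The labels give each replicate its own number, and since only the left muscle was taken, replicates were treated as separate animals.

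Per the submitters' processing notes, the authors used FastQC, Trim Galore, cutadapt and Bismark on the mouse genome mm10. Tool versions, settings and read-level filters are not given in the sources used here. The deposited values are counts, 1 pair of whole numbers per CpG cytosine and strand, giving methylated and unmethylated read calls without normalization. A cytosine is listed only where it had at least 1 call. RRBS reads that start at the same restriction site cannot be told from PCR copies, so calls are not independent molecules. Differences were therefore judged against the spread between libraries, and reported errors are standard deviations (SD) between libraries. In the F test that spread was in part borrowed from other features, as described below. The binomial counting error served only as the lowest error allowed in the F test, and depth is given as reads.

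Calls on the 2 strands of a CpG were summed. A CpG was used at a given day where each of the 16 libraries of that day had at least 10 reads, on the autosomes and chromosome X. The methylation level is the percent of calls that were methylated, and group values are means of library levels. Coordinates are mm10, counted from 1. The gene annotation available (GRCm38.p6, 34623 genes) gives gene starts and ends but neither strand nor exons. Promoters could therefore not be placed, and windows of 1000 bp with at least 3 covered CpGs took their place, as had been laid down for that case before the data were examined. Whether a site is exonic, intronic or in a UTR is not known here. Gene lists were tested on gene spans, from 1000 bp before to 1000 bp after each gene, with at least 3 covered CpGs. Of 585 entries in the 18 lists, 580 matched a gene, 1 of them by an older symbol.

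Groups were compared with a quasi-binomial logistic model and a two-sided F test, fitted to all 3 groups of a day, with Benjamini-Hochberg adjustment over all features tested and a false discovery rate of 0.05. The dispersion was moderated across features in the empirical Bayes manner of limma, with a floor of 1. Its prior was set apart in 4 classes of features, divided at 1, 3 and 10 mean calls of the rarer kind, and features in the extreme 0.01 tail of dispersion kept their own value. The moderation and the floor had been laid down before the data were examined, but the classes and the rule for the extreme tail were taken up later, after tests on simulated data in which true effects were known. With a single prior for all CpGs, 42.5 to 51.6% of calls were false. With the form used, 6.25 to 6.99% were false for CpGs and 0 to 6.25% for windows. These CpG rates come from simulations with many true changes, in which 256 to 329 CpGs were called. They do not give the chance that a single call in the real data is false. On simulated data a change of 20 points at a CpG was found in 39.5 to 59.0% of cases, and one of 10 points over a window in 35.5 to 50.5%. A change of 10 points at a CpG was found in only 2.5 to 4% and one of 5 points over a window in 1 to 9%. Counts of 0 therefore do not show that changes of such sizes were absent. An interaction term tested whether an effect differed between the days. Library means were compared by exact two-sided permutation tests. Gene lists were tested with camera in limma with a preset correlation of 0.01, then with an estimated correlation, and with fry, all two-sided and adjusted over the 18 lists.

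The 6 comparisons, the lists, the named-gene rule and the main alternatives were fixed before the data were examined. The rule named windows past the threshold, or else the 5 windows per direction with the smallest p, then list members past the threshold or the member with the smallest p, and CpGs past the threshold. A few of the windows and CpGs so chosen are not reported here. The alternatives fixed in advance were coverage minimums of 5 and 20 reads, strands kept apart, another dispersion floor, fits of only the 2 groups compared, lane tag as a covariate, replicate number as a block, windows with at least 5 CpGs, limma on log2 ratios with a pseudocount of 1, edgeR, and leaving out each library in turn. Some others, chosen after the data had been seen, are named as such in the closing section. Lane tags came from the deposited files. At 7 days all libraries carried lane tag 2, except 2 boldine libraries with tag 1. At 28 days the SCI vehicle libraries all carried tag 1, whereas sham and boldine libraries were divided evenly between tags 1 and 4. The file name of boldine replicate 6 of 28 days carries a letter otherwise found only on SCI vehicle files of that day. Its GEO label was followed, so boldine values of 28 days rest on that label, and results without this library are among those with each library left out. Chromosome Y and unplaced sequences were left out, since only the autosomes and chromosome X had been laid down for use, and CpGs under the coverage minimum were left out, since their levels are imprecise. Mitochondrial calls served only as a property of each library. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and edgeR 4.0.16.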

Results

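The data were methylation calls at CpG cytosines of mouse gastrocnemius DNA. Spinal cord injury paralyses the muscles below the lesion, and the gastrocnemius then loses mass. Boldine is an alkaloid of the boldo tree that blocks connexin hemichannels, the membrane pores that denervated muscle fibres form anew. The series set out to examine what boldine does to this muscle after the injury. At each day there were 4 sham, 6 SCI vehicle and 6 SCI boldine libraries. In order of replicate number, sham libraries of 7 days held 94922323, 85945104, 83926874 and 81543640 CpG calls. The SCI vehicle libraries of that day held 87986744, 83204919, 71991654, 86063735, 67769436 and 76648886 calls, and the boldine libraries 103770169, 87557910, 76986360, 87781866, 76858799 and 69511723. At 28 days sham libraries held 101796769, 89124516, 83640054 and 80495959 calls. For SCI vehicle the totals were 97974147, 102157374, 87837212, 98513387, 79245309 and 90261786, and for boldine 68282189, 76012658, 69242777, 97472367, 39188276 and 66614029. The median depth per listed CpG was 17 to 29 reads, and 1084720 to 1315291 CpGs of a library had at least 10 reads. 1013766 CpGs at 7 days and 1007966 at 28 days were covered in every library of the day.

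With each CpG counted alike, mean methylation over these CpGs hardly differed between groups. At 7 days it was 39.9% ± 0.110 (SD, n = 4) in sham, 39.9% ± 0.126 (SD, n = 6) in SCI vehicle and 39.9% ± 0.185 (SD, n = 6) in SCI boldine muscle. At 28 days it was 39.8% ± 0.190 (SD, n = 4), 39.6% ± 0.785 (SD, n = 6) and 39.8% ± 0.0698 (SD, n = 6). SCI vehicle minus sham was 0.0406 points at 7 days (exact permutation p = 0.571) and −0.243 at 28 days (exact p = 0.895). Boldine minus SCI vehicle was −0.0353 points at 7 days (exact p = 0.710) and 0.240 at 28 days (exact p = 0.898). Boldine minus sham was 0.00530 points (exact p = 0.990) and −0.00280 points (exact p = 0.990) at the same days. SCI vehicle replicate 2 of 28 days stood apart from the rest of its group at 38.0%. Without it the 28-day differences were 0.0743 points for SCI vehicle minus sham and −0.0771 for boldine minus SCI vehicle. Other single libraries also turned the sign of these small differences, and the closing section gives the ranges. Weighted by reads instead, differences from sham were larger, at 0.502 points for SCI vehicle (exact p = 0.381) and 0.528 for boldine (exact p = 0.476) at 7 days, and −0.686 (exact p = 0.286) and −0.602 (exact p = 0.105) at 28 days. Boldine minus SCI vehicle was then 0.0252 and 0.0833 points (exact p = 0.961 and 0.866). No difference had an exact p under 0.05 by either weighting.

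**Figure D1:**
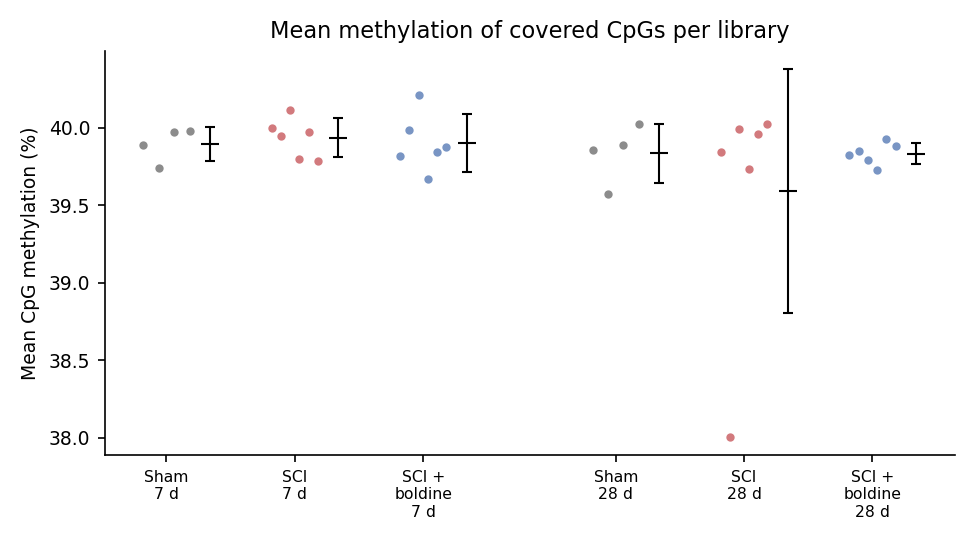
Mean methylation of each library (percent, vertical axis) by group and day (horizontal axis), with each point 1 library and bars giving the group mean ± SD. SCI vehicle replicate 2 of 28 days lies at 38.0%, below every other library.

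What the injury changed within 7 days was examined by comparing SCI vehicle with sham muscle. Mymx, whose product myomixer lets myoblasts fuse, had a higher level over its gene span (chromosome 17, 45600961 to 45602196), at 63.8% ± 1.56 (SD, n = 6) against 59.6% ± 1.33 (SD, n = 4) in sham. Its difference of 4.26 points had an adjusted p of 0.0332 adjusted over the list alone and 0.99995 over all gene spans, with 6 of 6 injured libraries above every sham library. Windows inside Rasip1, a gene of blood vessel formation, and Ptch1, the Hedgehog receptor, had the smallest p values among higher windows. For Rasip1 (chromosome 7, 45632001 to 45633000) the level was 44.6% ± 0.668 (SD, n = 6) against 39% ± 2.67 (SD, n = 4) in sham, and for Ptch1 (chromosome 13, 63513001 to 63514000) it was 63.6% ± 3.75 (SD, n = 6) against 55.2% ± 3.80 (SD, n = 4). On the lower side, a window of Hspa1a (chromosome 17, 34970001 to 34971000), which encodes an inducible heat-shock protein, had 24.4% ± 4.79 (SD, n = 6) against 33.1% ± 1.59 (SD, n = 4). None of these windows passed the test. Also without passing, differences were 6.47 points in Cers1, a ceramide synthase gene, 7.06 in Camta1 and 5.15 in Septin9, a septin of the cytoskeleton. They were −6.91 points in Ncf4, a subunit of the phagocyte oxidase, −7.97 in the lipid flippase gene Atp8b1, −7.18 in the sodium pump gene Atp1a4 and −6.43 in Gm19951.

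Gene groups showed no common shift at 7 days, where none of the 18 lists passed camera (smallest adjusted p = 0.986). Of 38 contractile genes, 15 had a higher mean in SCI vehicle muscle, none passed, and Tnnt3, fast troponin T, had the smallest p at −6.13 points. Of 40 atrophy and autophagy genes, 23 were higher in mean and none passed, with Atg7, which starts autophagosome formation, at 4.01 points. Among 40 matrix and fibrosis genes 25 were higher in mean and none passed, with Tgfb3 at 3.91 points. For 23 connexin, pannexin and related channel genes, 13 were higher in mean and none passed, with the ATP-gated channel gene P2rx4 at 2.94 points. Of 39 Hox genes 28 were higher in mean and none passed, with Hoxd3 at 2.83 points. Gene spans as a whole also leaned higher, with a mean difference of 0.257 points over 23004 spans. Of 995 spans with an unadjusted p under 0.05 by the F test, 705 were higher. Of 21 immune cell markers 12 were higher in mean and none passed, with the macrophage gene Adgre1 at −1.60 points. Differences without a pass also stood at −2.79 points for the insulin receptor substrate gene Irs2, 4.68 for Rcan1, a calcineurin regulator, and −5.11 for Dpp4.

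By the quasi-binomial F test 0 CpGs and 0 windows passed, and 54972 CpGs and 4661 of 97766 windows had an unadjusted p under 0.05, with limma and edgeR also at 0 windows. The smallest adjusted p was 0.672 among CpGs and 0.9998 among windows. Of 526 list gene spans tested, 1 passed when adjusted over the list alone and 0 when adjusted over all gene spans tested, and 37 had an unadjusted p under 0.05. The Mymx call ended when any 1 of sham replicates 2, 3 and 4 or SCI vehicle replicates 2, 3 and 4 was left out, with adjusted p from 0.0811 to 0.161, and at a coverage minimum of 5 reads (0.108, next to 0.0247 at 20 reads). In 9 of the 18 lists the median, the mean and the camera direction did not share a sign.

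The same comparison at 28 days addressed the longer-lasting state of the paralysed muscle. A CpG inside Prex1 (chromosome 2, 166610318 to 166610319), a gene for an activator of the Rac GTPase, fell from 91.8% ± 1.24 (SD, n = 4) in sham to 77.0% ± 3.41 (SD, n = 6) in SCI vehicle muscle. Over whole gene spans, Clock, the core circadian transcription factor gene (chromosome 5, 76209868 to 76305603), had a higher level at 26.1% ± 1.24 (SD, n = 6) against 21.3% ± 2.02 (SD, n = 4) in sham. Tbx1, a transcription factor gene of muscle development (chromosome 16, 18580979 to 18590671), was higher at 30.2% ± 0.731 (SD, n = 6) against 26.2% ± 0.408 (SD, n = 4). The span of Myl2, the slow-fibre myosin regulatory light chain gene (chromosome 5, 122092724 to 122113473), was lower at 73.6% ± 2.25 (SD, n = 6) against 78.4% ± 1.49 (SD, n = 4). These 3 spans passed only when adjusted over the list alone, with p of 0.00237 for Clock (4.79 points), 0.00790 for Tbx1 (4.08) and 0.0393 for Myl2 (−4.78), and 0.552, 0.552 and 0.689 over all gene spans. For each, 6 of 6 SCI vehicle libraries lay beyond every sham library.

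At the Prex1 CpG the difference was −14.8 points, with p = 3.91e-08 and an adjusted p of 0.0394 (quasi-binomial F test), at a median depth of 144 reads. This p rests on a moderated dispersion of 1.60, below the CpG's own value of 2.02. The prior of its class had 52.6 degrees of freedom, against 13 from the libraries at this CpG. The spread between libraries at this CpG itself thus had the smaller weight in the test. All 6 SCI vehicle libraries, at 72.9 to 82.1%, lay below the 4 sham libraries, at 90.2 to 93.1%. Boldine-treated muscle of that day had 77.8% ± 8.07 (SD, n = 6), which is −14.1 points from sham (adjusted p = 0.208). At 7 days, where it did not pass, SCI vehicle minus sham was −7.79 points at this CpG. By the F test the unadjusted p was 0.000861 there, and the p adjusted over all CpGs was 0.903. Over all injured libraries of 28 days, boldine included, this CpG differed from sham by −14.5 points, covered CpGs 8 and 36 bp further on by −7.17 and −14.9, and those 92 and 100 bp before it by −0.469 and −0.695. Within lane tag 1, with 6 against 2 libraries, the Prex1 difference was −14.6 points.

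**Figure D2:**
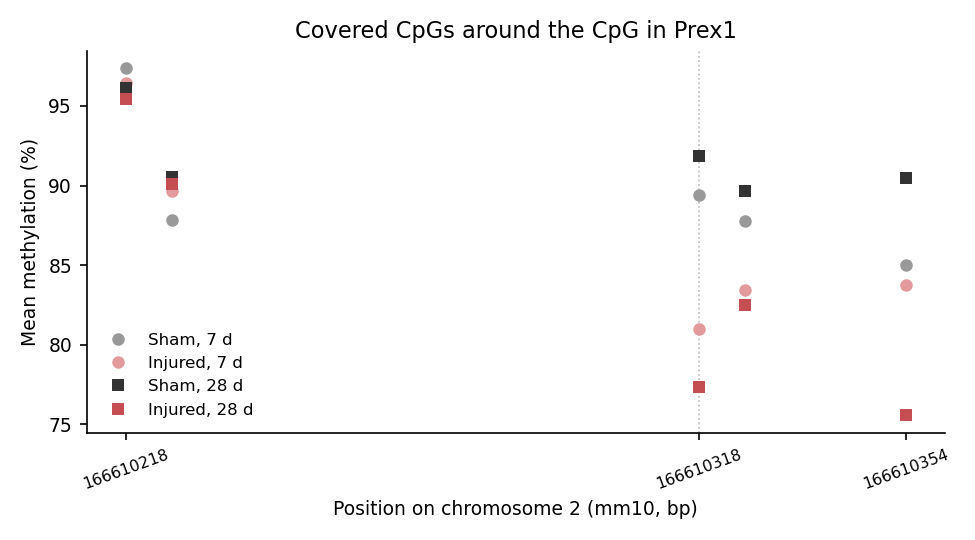
Mean methylation (percent, vertical axis) at the 5 covered CpGs of a part of Prex1 against position on chromosome 2 in mm10 (horizontal axis), for sham and injured libraries at 7 and 28 days. Injured muscle lies lower at the CpG at 166610318 at both days.

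**Figure D3:**
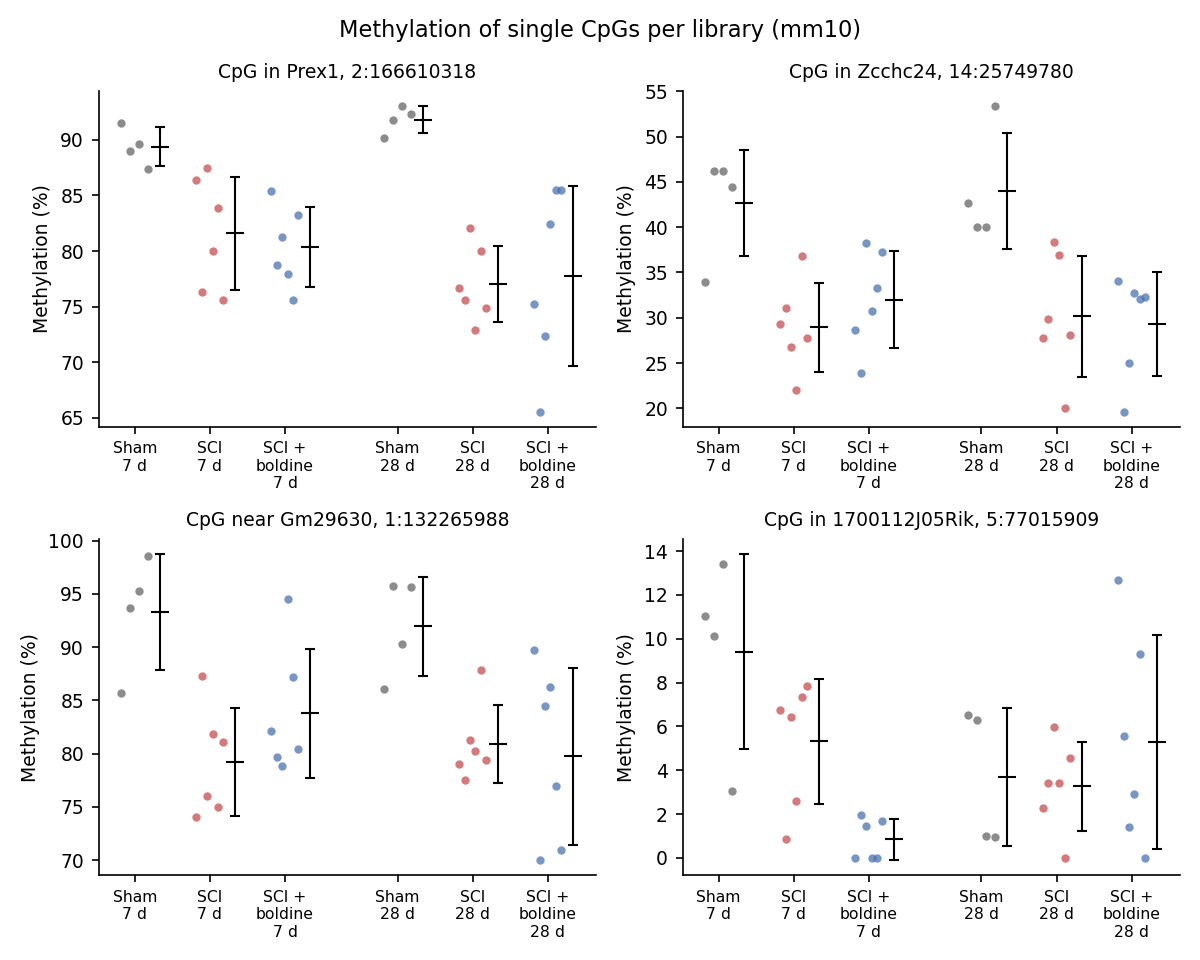
Methylation (percent, vertical axis) at 4 CpGs, in Prex1, in Zcchc24, near Gm29630 and in 1700112J05Rik, by group and day (horizontal axis), with a point per library and bars for the mean ± SD. At the Prex1 CpG at 28 days, SCI vehicle libraries lie at 72.9 to 82.1% and sham libraries at 90.2 to 93.1%.

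Among windows, Ranbp3l, which encodes a nuclear export factor, had the smallest p. Its window (chromosome 15, 8967001 to 8968000) had 23.9% ± 4.30 (SD, n = 6) against 37.1% ± 1.61 (SD, n = 4) in sham, a difference of −13.2 points that did not pass (adjusted p = 0.0950). A window near the end of Hoxc4 (chromosome 15, 103035001 to 103036000), a body-patterning gene, had 41.0% ± 3.37 (SD, n = 6) against 30.4% ± 5.59 (SD, n = 4). One of Spry1 (chromosome 3, 37642001 to 37643000), which restrains growth factor signalling in satellite cells, had 42.5% ± 1.74 (SD, n = 6) against 34.9% ± 1.47 (SD, n = 4). Without a pass, the window inside Cdh13, the T-cadherin gene, differed by 8.29 points, one 23806 bp from Gm35572 by 13.9, one 1424 bp from Gm35620 by 8.73 and one 7859 bp from Gm30866 by −14.9. Lower windows inside genes that did not pass were those of Prex1 at −8.27 points and the translation initiation gene Eif4g1 at −9.53.

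Of 39 Hox genes at 28 days, 24 had a higher mean in SCI vehicle muscle and none passed, with Hoxc12 at 3.88 points. The camera test of this list gave an adjusted p of 0.351. Endothelial and mural cell markers, of which 15 of 23 were higher in mean and none passed, had a camera adjusted p of 0.351, with Vwf, a protein of the vessel lining, at −1.94 points. Of 30 genes of the neuromuscular junction 13 were higher in mean and none passed, with Hdac9 at 2.84 points. Among 21 immune cell markers 8 were higher in mean, none passed, and the myeloid factor gene Spi1 stood at 4.55 points. Of 44 mitochondrial genes 14 were higher in mean and none passed, with Sdha at 0.318 points. Gene spans as a whole also leaned lower, with a mean difference of −0.377 points over 23039 spans. Of 1370 spans with an unadjusted p under 0.05 by the F test, 316 were higher. These values include SCI vehicle replicate 2, which stood apart, and are not given without it here. Leaving it out turned the mean difference over CpGs from −0.243 to 0.0743 points, so this library may carry part of the lean. The calcium-entry gene Stim1 stood at −6.01 points, Stat3 at −1.91 and the imprinted gene Zrsr1 at 2.65, without passing. In this group SCI vehicle replicate 2 had lower immune marker levels, such as 65.4% at Itgam against 77.1% ± 2.26 in the other SCI vehicle libraries (SD, n = 5).

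In all, 1 CpG and 0 windows passed the quasi-binomial F test, 55473 CpGs and 5006 windows had an unadjusted p under 0.05, and limma and edgeR gave 0 windows. Of 528 list gene spans tested, 3 passed when adjusted over the list alone and 0 when adjusted over all gene spans tested, and 37 had an unadjusted p under 0.05. The Prex1 call ended with lane tag as a covariate (adjusted p = 0.168, in a range of 3.44e-07 to 0.168 over settings with strands summed and all libraries kept), where the effect stayed at −1.23 ± 0.232 log odds (standard error), next to −1.20 ± 0.209 without lane, and only the error grew. It also ended with strands kept apart, where the smallest adjusted p of any site was 0.444, and when any 1 of sham replicates 1 to 4 or SCI vehicle replicates 1, 4 and 6 was left out, at 0.102 to 0.583. The Ranbp3l window passed without SCI vehicle replicate 3 (0.0137) or 6 (0.0217) and at a coverage minimum of 5 reads (0.0359, in a range of 0.0359 to 0.973). Clock and Tbx1 held without each library (adjusted p 0.00135 to 0.0143 and 0.00768 to 0.0338), Tbx1 did not at a minimum of 20 reads (0.191, next to 0.0180 at 5), and Myl2 ended at 5 reads (0.0883, next to 0.0306 at 20) and when any 1 of sham replicates 1, 3 and 4 or SCI vehicle replicates 2, 3 and 4 was left out (0.0698 to 0.177). Within lane tag 1 the differences were 4.66 points for Clock, 4.03 for Tbx1 and −5.39 for Myl2. With lane tag as a covariate Clock and Tbx1 held (adjusted p = 0.0127 and 0.00715) and Myl2 ended (adjusted p = 0.125; −0.266 ± 0.0676 without and −0.246 ± 0.0791 log odds with lane, standard error). No list passed camera (smallest adjusted p = 0.351), and the signs of median, mean and camera direction differed in 9 lists.

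Boldine was set against vehicle in injured mice to find what the drug changed. At 7 days the span of Sdhb, the iron-sulphur subunit gene of succinate dehydrogenase (chromosome 4, 140961271 to 140979198), had a lower level with boldine, at 12.6% ± 1.29 (SD, n = 6) against 16.1% ± 2.03 (SD, n = 6) with vehicle. Dpp4, which encodes a peptidase found on stromal progenitor cells (chromosome 2, 62330073 to 62412315), had a higher level, at 72.4% ± 2.96 (SD, n = 6) against 66.0% ± 2.51 (SD, n = 6). Sdhb differed by −3.53 points and Dpp4 by 6.43, with p of 0.0395 and 0.0487 adjusted over the list alone and 0.647 and 0.648 over all gene spans, and 5 of 6 boldine libraries lay beyond every vehicle library at either gene. Among the named windows, the largest difference was in Sema3f (chromosome 9, 107695001 to 107696000), the gene of a secreted axon-guidance protein, at 79.9% ± 1.96 (SD, n = 6) against 68.9% ± 4.04 (SD, n = 6), and it did not pass (adjusted p = 0.456).

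Other windows that did not pass included 7.03 points in Ablim1, an actin-binding protein gene, and 7.49 in Ebf1, a transcription factor gene of B cells and fat. In windows 50331 and 20331 bp from Zfp64, the gene nearest to them, differences were 6.20 and 3.78 points. Lower values that did not pass were −0.564 points for the G protein gene Gna11, −0.858 for the aggrecanase gene Adamts5, −7.00 for Soat2, which esterifies cholesterol, and −9.28 for Rgs3. A window 427694 bp from D3Ertd751e differed by −3.58 points. Boldine targets connexin hemichannels, and of 23 connexin, pannexin and related channel genes 16 had a higher mean with boldine and none passed, with Stim1 at −4.51 points. Of 38 contractile genes 26 were higher in mean and none passed, with parvalbumin, Pvalb, at 4.93 points, and camera gave an adjusted p of 0.747. Of 30 inflammation genes 13 were higher in mean and none passed, with Il6 at −2.93 points. Among 21 immune markers 8 were higher in mean and none passed, with Tyrobp, a signalling adaptor of myeloid cells, at −6.91 points. Of 40 atrophy and autophagy genes 17 were higher in mean and none passed, with Map1lc3b at 5.68 points.

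No CpG or window passed the quasi-binomial F test (0 and 0, with 55578 CpGs and 5489 windows at an unadjusted p under 0.05), nor did limma or edgeR call a window (0 each). Of 526 list gene spans tested, 2 passed when adjusted over the list alone and 0 when adjusted over all gene spans tested, and 41 had an unadjusted p under 0.05. Sema3f passed without SCI vehicle replicate 4 (adjusted p = 0.0179, in a range of 0.0179 to 0.928). The Sdhb call ended when any 1 of SCI vehicle replicates 1, 2, 4 and 5 or boldine replicates 1, 3, 4 and 5 was left out (0.0585 to 0.151), and that of Dpp4 when any 1 of SCI vehicle replicates 2 to 5 or boldine replicates 1 to 4 and 6 was (0.0551 to 0.160) and at 5 reads (0.0506, next to 0.0400 at 20), whereas Tyrobp passed at 20 reads (0.0437, in a range of 0.0437 to 0.105). Within lane tag 2 the differences were −3.46 points for Sdhb and 7.86 for Dpp4, and with lane tag as a covariate Dpp4 held (adjusted p = 0.0194) and Sdhb ended (adjusted p = 0.161; −0.306 ± 0.0760 without and −0.297 ± 0.0878 log odds with lane, standard error). Median, mean and camera direction differed in sign in 3 lists, and no list passed camera (smallest adjusted p = 0.747).

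At 28 days, 4 list genes differed between boldine and vehicle in injured muscle when adjusted over the list alone. Chrng, the fetal acetylcholine receptor subunit gene that muscle turns on again when it loses its nerve (chromosome 1, 87205811 to 87211835), had 78.6% ± 2.27 (SD, n = 6) with boldine against 70.5% ± 3.43 (SD, n = 6) with vehicle, and sham had 75.2% ± 1.91 (SD, n = 4). The span of Clock was lower, at 21.6% ± 1.51 (SD, n = 6) against 26.1% ± 1.24 (SD, n = 6), next to 21.3% ± 2.02 (SD, n = 4) in sham. Egr2 (chromosome 10, 67534469 to 67542188), the transcription factor gene that drives myelination in Schwann cells, was lower at 3.86% ± 0.433 (SD, n = 6) against 5.01% ± 0.492 (SD, n = 6). Irs2 (chromosome 8, 10984681 to 11008929), an insulin receptor substrate gene, was higher at 19.4% ± 1.07 (SD, n = 6) against 17.0% ± 1.17 (SD, n = 6).

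The differences were 8.12 points for Chrng, −4.48 for Clock, −1.14 for Egr2 and 2.41 for Irs2. Their p values were 0.00570, 0.00107, 0.00529 and 0.0231 adjusted over the list alone and 0.403, 0.403, 0.525 and 0.566 over all gene spans. All 6 boldine libraries lay beyond every vehicle library at Chrng and Clock, and 5 of 6 did so at Egr2 and Irs2. Chrng, Clock and Egr2 held without each single library, the one that stood apart included, with adjusted p of 0.00308 to 0.0354, 0.000939 to 0.00631 and 0.00125 to 0.0180. Within lane tag 1, with 3 against 6 libraries, the differences were 9.86 points for Chrng, −4.67 for Clock, −0.820 for Egr2 and 2.05 for Irs2. With lane tag as a covariate Chrng, Clock and Egr2 held (adjusted p = 0.00338, 0.00524 and 0.0375) and Irs2 ended (adjusted p = 0.0948; 0.156 ± 0.0376 without and 0.150 ± 0.0427 log odds with lane, standard error). Irs2 lost its call when any 1 of SCI vehicle replicates 1, 2, 4 and 6 or boldine replicates 1, 2, 5 and 6 was left out (0.0511 to 0.0876). At a minimum of 20 reads Egr2 ended, its difference falling to −0.534 points (0.0524, next to 0.00581 at 5 reads), and Stim1 passed (0.0370, in a range of 0.0358 to 0.0724).

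**Figure D4:**
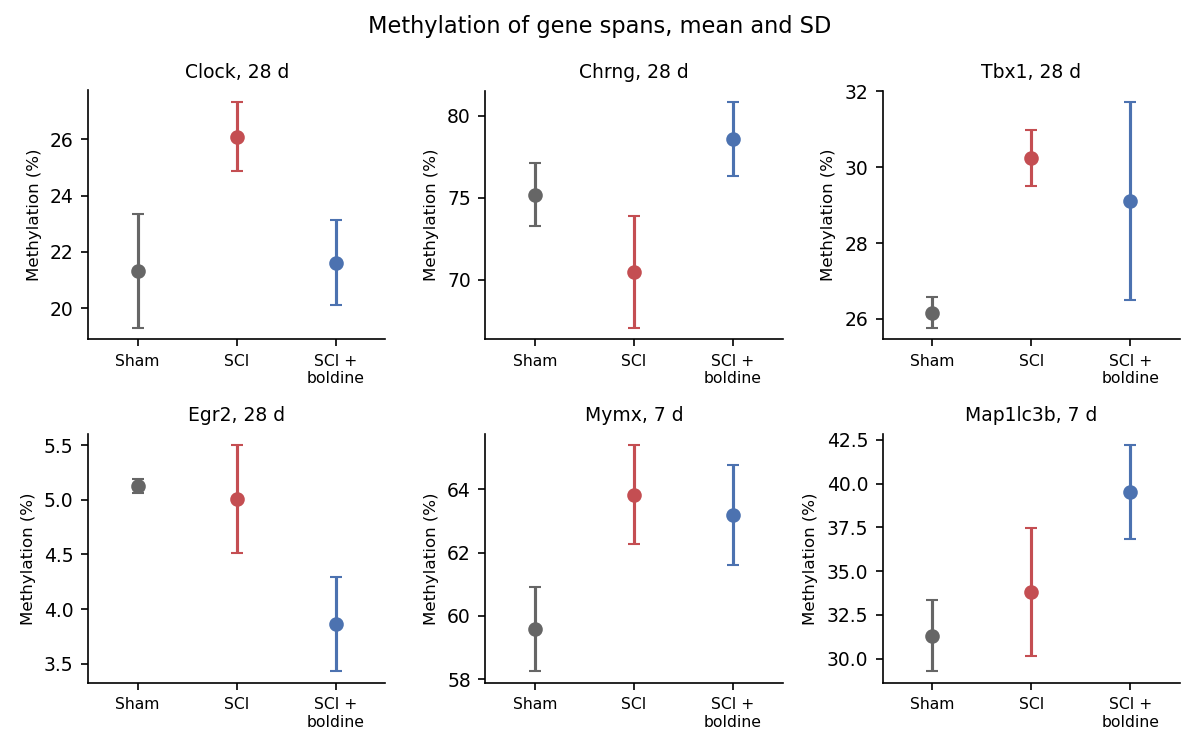
Methylation (percent, vertical axis) over the gene spans of Clock, Chrng, Tbx1 and Egr2 at 28 days and of Mymx and Map1lc3b at 7 days, by group (horizontal axis), with a point for each group mean and bars for the SD. Clock averages 26.1% in SCI vehicle muscle against 21.3% in sham and 21.6% with boldine.

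Among windows that did not pass, the difference was 5.26 points in the ciliary kinase gene Nek8. Windows outside genes differed by 5.54 points at 44624 bp from Pramel35, 4.53 at 15395 bp from Gm40857 and 5.73 at 910 bp from Cntfr, the receptor gene for ciliary neurotrophic factor. The window of Hdac5 (chromosome 11, 102224001 to 102225000), a histone deacetylase that acts in muscle gene control, had 12.2% ± 1.44 (SD, n = 6) against 17.6% ± 2.19 (SD, n = 6). Values were −3.89 points at 180 bp from the mRNA export gene Thoc1, −7.05 for Dlx6os1, −11 for Gm20675 and −1.65 for Zfp516. Of 23 connexin, pannexin and related channel genes 13 had a higher mean and none passed, with Stim1 at 5.69 points. Of 30 neuromuscular junction genes 12 were higher in mean and only Chrng passed within its list. Among 23 endothelial and mural markers 11 were higher in mean and none passed, with the endothelial receptor gene Kdr at −4.19 points. Of 39 Hox genes 19 were higher in mean and none passed, with Hoxc12 at −4.03 points.

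By the quasi-binomial F test 0 CpGs and 0 windows passed, 55334 CpGs and 4862 windows had an unadjusted p under 0.05, and limma and edgeR also gave 0 windows. Of 528 list gene spans tested, 4 passed when adjusted over the list alone and 0 when adjusted over all gene spans tested, and 38 had an unadjusted p under 0.05. The sign of median, mean or camera direction differed in 5 lists, and none of the 18 passed camera (smallest adjusted p = 0.528). A CpG in Cdk8 passed without SCI vehicle replicate 2 (adjusted p = 0.0276), and the Gm20675 window without boldine replicate 2 (0.0480, in a range of 0.0480 to 0.9999).

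How far treated injured muscle lay from uninjured muscle was asked by comparing boldine with sham. At 7 days a CpG inside 1700112J05Rik (chromosome 5, 77015909 to 77015910), a long non-coding RNA gene, fell from 9.40% ± 4.45 (SD, n = 4) in sham to 0.846% ± 0.941 (SD, n = 6) with boldine, and SCI vehicle muscle had 5.32% ± 2.87 (SD, n = 6). The span of Map1lc3b (chromosome 8, 121590438 to 121598760), which encodes the autophagosome protein LC3B, was higher at 39.5% ± 2.68 (SD, n = 6) against 31.3% ± 2.04 (SD, n = 4) in sham. Levels were higher also at Acadm, a fatty acid oxidation enzyme gene (chromosome 3, 153922353 to 153944643), with 48.6% ± 2.12 (SD, n = 6) against 41.9% ± 4.05 (SD, n = 4), and at the growth factor gene Tgfb3 (chromosome 12, 86056743 to 86079041), with 80.0% ± 2.22 (SD, n = 6) against 74.1% ± 2.31 (SD, n = 4). Tpm1, a tropomyosin gene (chromosome 9, 67022590 to 67049672), had 19.5% ± 1.5 (SD, n = 6) against 15.8% ± 1.22 (SD, n = 4). Nfil3, a repressor in the clock output (chromosome 13, 52967209 to 52982878), was lower at 9.11% ± 0.364 (SD, n = 6) against 10.1% ± 0.295 (SD, n = 4).

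The 1700112J05Rik CpG differed by −8.56 points, with p = 1.23e-08 and an adjusted p of 0.0125 (quasi-binomial F test), at a median depth of 91.5 reads. This p rests on the dispersion of the CpG's class, 1.32, which replaced its own larger value of 1.60. The spread between libraries at this CpG itself thus had no weight in the test. All 6 boldine libraries, at 0 to 1.96%, lay below the 4 sham libraries, at 3.06 to 13.4%. Within lane tag 2, with 4 against 4 libraries, the difference at this CpG was −8.13 points, and at 28 days boldine minus sham was 1.60 points (adjusted p = 0.979). List genes differed by 8.20 points at Map1lc3b, 6.66 at Acadm, 5.89 at Tgfb3, 3.73 at Tpm1 and −0.988 at Nfil3. Their p values adjusted over the list alone were 0.0116, 0.0399, 0.0122, 0.0181 and 0.0120, and over all gene spans 0.397, 0.397, 0.397, 0.397 and 0.397. At Map1lc3b and Nfil3 6 of 6 boldine libraries lay beyond every sham library, and 5 of 6 did at Acadm, Tgfb3 and Tpm1. Within lane tag 2 the differences were 9.05 points at Map1lc3b, 6.54 at Acadm, 5.21 at Tgfb3, 4.35 at Tpm1 and −1.02 at Nfil3. With lane tag as a covariate Map1lc3b, Tpm1 and Nfil3 held (adjusted p = 0.0120, 0.00861 and 0.0308), while Acadm ended (adjusted p = 0.130; 0.269 ± 0.0668 without and 0.267 ± 0.0759 log odds with lane, standard error), as did Tgfb3 (adjusted p = 0.0771; 0.330 ± 0.0725 without and 0.296 ± 0.0797 log odds with lane, standard error).

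The largest difference among the named windows was inside Igf1r (chromosome 7, 68012001 to 68013000), the receptor gene of insulin-like growth factor, with 58.7% ± 6.45 (SD, n = 6) against 36.1% ± 7.90 (SD, n = 4) in sham, and it did not pass (adjusted p = 0.318). Windows of Tie1 (chromosome 4, 118489001 to 118490000), an endothelial receptor gene, and Spag7 (chromosome 11, 70663001 to 70664000) had 46.1% ± 3.77 (SD, n = 6) against 57.2% ± 1.92 (SD, n = 4) and 48.2% ± 4.25 (SD, n = 6) against 61.2% ± 7.93 (SD, n = 4), also without passing. Values that did not pass were 3.79 points for Sycp2, 11 for Zbtb10 and 8.66 at 216 bp from the iodide transporter gene Slc5a5. For the protease gene Hpn the value was −7.35 points, at 16937 bp from Aadacl4fm4 it was −5.02 and for the ubiquitin gene Ubb −1.57. Of 40 atrophy and autophagy genes 23 had a higher mean, and only Map1lc3b passed within its list. Of 44 mitochondrial genes 21 were higher in mean and only Acadm passed. Among 40 matrix genes 25 were higher in mean and only Tgfb3 passed. Of 23 connexin, pannexin and related channel genes 12 were higher in mean and none passed, with Panx2, a pannexin, at 5.03 points. Of 30 junction genes 16 were higher in mean and none passed, with the adult receptor subunit gene Chrne at −4.72 points.

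In this comparison 1 CpG and 0 windows passed the quasi-binomial F test, and limma and edgeR gave 0 windows. Those at an unadjusted p under 0.05 were 56167 CpGs and 5796 windows. Of 526 list gene spans tested, 5 passed when adjusted over the list alone and 0 when adjusted over all gene spans tested, and 58 had an unadjusted p under 0.05. The 1700112J05Rik call ended with lane tag as a covariate (adjusted p = 0.823, in a range of 0.00165 to 0.823), where the effect shrank from −2.59 ± 0.609 to −2.12 ± 0.610 log odds (standard error). It also ended with strands apart (smallest adjusted p of any site 0.566), and when any 1 of sham replicates 1 to 3 or boldine replicates 1, 4 and 5 was left out (0.0780 to 0.320). Tpm1 ended without sham replicate 1 or 3 (0.0634 to 0.0775), Map1lc3b without sham replicate 1 or 4 (0.0608 to 0.0694), Tgfb3 without sham replicate 2 or 4 (0.0505 to 0.0546), Nfil3 without sham replicate 3 (0.0612) or at 5 reads (0.0770, next to 0.00477 at 20), and Acadm when any 1 of sham replicates 1, 3 and 4 or boldine replicates 1, 3, 5 and 6 was left out (0.0636 to 0.253). The Igf1r and Spag7 windows passed without sham replicate 1 (0.0488 each, in ranges of 0.0488 to 0.737 and 0.0488 to 0.804). In 10 lists median, mean and camera direction differed in sign, and no list passed camera (smallest adjusted p = 0.944).

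At 28 days, 41 genes of atrophy, ubiquitin ligases and autophagy lay lower as a group with boldine than in sham muscle. By camera the list had an adjusted p of 0.0494, with adjusted p = 0.447 with an estimated correlation. Only 10 of the genes had a higher mean, and their median difference was −0.370 points and the mean −0.487. Foxo3, a transcription factor gene that drives atrophy genes, had 27.4% ± 0.809 (SD, n = 6) against 28.8% ± 1.06 (SD, n = 4) in sham. Mul1, a mitochondrial ubiquitin ligase gene, had 30.4% ± 1.95 (SD, n = 6) against 33.3% ± 1.39 (SD, n = 4), and the F-box gene Fbxo31 had 74.4% ± 1.04 (SD, n = 6) against 76.3% ± 1.22 (SD, n = 4). In SCI vehicle muscle of that day the same list had a median of −0.507 points against sham, with 16 genes higher in mean (camera adjusted p = 0.615), so a lower median was not particular to boldine. The mean difference over all gene spans was −0.377 points for SCI vehicle and −0.127 for boldine against sham, so part of either shift was shared by genes in general. The SCI vehicle values of that day include replicate 2, which stood apart. None of these genes passed on its own, and by fry the list had an adjusted p of 0.293.

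Egr2, the myelination factor gene, was lower over its span at 3.86% ± 0.433 (SD, n = 6) against 5.13% ± 0.0667 (SD, n = 4) in sham. The difference of −1.26 points had an adjusted p of 0.00482 adjusted over the list alone and 0.999 over all gene spans, with 6 of 6 boldine libraries below every sham library. Within lane tag 1 it was −0.991 points, and the call held with lane tag as a covariate (adjusted p = 0.00304). Windows that did not pass included Spry1 (chromosome 3, 37642001 to 37643000), with 44.6% ± 4.09 (SD, n = 6) against 34.9% ± 1.47 (SD, n = 4), and Ranbp3l (chromosome 15, 8967001 to 8968000), with 24.9% ± 2.53 (SD, n = 6) against 37.1% ± 1.61 (SD, n = 4). Windows outside genes differed by 13.3 points at 1055 bp from Hotair, a non-coding RNA gene of the Hoxc cluster, 9.67 at 11157 bp from the integrin gene Itga3, 9.32 at 1424 bp from Gm35620 and −9.10 at 9109 bp from Gm37548. Values inside genes were 8.18 points for Abca3, −7.29 for Prex1, −4.29 for Tbx2 and −2.24 for the proton pump gene Atp6v1e1, none of which passed.

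Of 33 growth, IGF and mTOR genes 5 had a higher mean and none passed, with Mknk2 at −1.39 points and a camera adjusted p of 0.358. Of 39 contractile genes 16 were higher in mean and none passed, with Lmod3, a thin-filament gene, at −4.72 points. Among 41 matrix genes 20 were higher in mean and none passed, with the collagen gene Col1a2 at 10.7 points, a value from 3 CpGs with a sham SD of 14.4 that ran from 5.54 to 16.4 without single libraries. Of 23 channel genes 8 were higher in mean and none passed, with Gja1, which encodes connexin 43, at 4.02 points. Among 39 Hox genes 22 were higher in mean and none passed, with Hoxc4 at 4.20 points. Of 30 myogenic genes 13 were higher in mean and none passed, with Mef2a at −4.09 points.

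By the quasi-binomial F test 0 CpGs and 0 windows passed, with 51279 CpGs and 3633 windows at an unadjusted p under 0.05 and 0 windows by limma. Only edgeR called 1 window, in Mid1 (chromosome X, 169987001 to 169988000), with a log2 ratio of −1.75 and an adjusted p of 0.0214. Of 528 list gene spans tested, 1 passed when adjusted over the list alone and 0 when adjusted over all gene spans tested, and 24 had an unadjusted p under 0.05. The call of the atrophy list ended also at a minimum of 20 reads and without each library except boldine replicate 1, and Egr2, which held without each library (0.00114 to 0.0201), ended at 20 reads with a difference of −0.542 points (0.0818, next to 0.00727 at 5). Median, mean and camera direction differed in sign in 3 lists.

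Whether an effect differed between 7 and 28 days was tested directly, and no window passed. Among named windows, the largest such differences for the injury were 23.8 points at 34914 bp from Sh3bp4, an endocytosis gene, where SCI minus sham was 9.33 at 28 and −14.5 at 7 days, and 19.3 at 1869 bp from Frat2, a Wnt pathway gene. A window 104508 bp from Fign, a microtubule-severing gene, differed by −14.2 points and one in Nme2, a nucleoside kinase gene, by −11.6. For boldine the values were 9.62 points at 3400 bp from Lalba, −8.43 in the tubulin kinase gene Ttbk1 and −10.3 at 4494 bp from Mrps23, a mitochondrial ribosome gene. Of 94173 windows, 0 passed for the injury and 0 for boldine by the F test, with 0 by limma for each. Their smallest adjusted p values were 0.9997 and 0.705, and 4437 and 4736 windows had an unadjusted p under 0.05. On simulated data such a test found a difference of 10 points in 5.5% of windows, so few changes of this size or smaller could be detected. The single CpG called at 28 days for SCI vehicle against sham, in Prex1, had the same sign at 7 days (1 of 1), as it did in 59 of 100 splits of the 7-day libraries, the real one included, so this share carries little information. No CpG was called for boldine against SCI vehicle at either day, so no such share exists for it.

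Over all 6 comparisons, list medians moved by less than 1 point. The mean difference over all gene spans moved as well. At 7 days it was 0.257 points for SCI vehicle against sham, 0.0247 for boldine against SCI vehicle and 0.282 for boldine against sham. In the same order it was −0.377, 0.250 and −0.127 points at 28 days. Counts of list genes higher in mean are to be read against these shifts. Contractile genes (38 genes at 7 days) had a median sham level of 50.3% and median differences of −0.426 to 0.385 points. The 23 regulators of fast and slow fibres had a sham median of 21.2%, and their median differences ran from −0.132 to 0.215 points. For 30 genes of the neuromuscular junction the sham median was 42.1% and the median difference −0.437 to 0.268 points. Connexin, pannexin and related channel genes (23 genes at 7 days) had a median sham level of 31.4% and median differences of −0.609 to 0.181 points. The 40 atrophy and autophagy genes had a sham median of 14.8%, and their median differences ran from −0.507 to 0.345 points. For 44 mitochondrial genes the sham median was 14.3% and the median difference −0.210 to 0.0556 points. Myogenic regulators and satellite cell genes (29 genes at 7 days) had a median sham level of 18.3% and median differences of −0.113 to 0.110 points. The 34 growth, IGF and mTOR genes had a sham median of 14.5%, and their median differences ran from −0.435 to 0.102 points. For 19 clock genes the sham median was 13.8% and the median difference −0.498 to 0.392 points. The smallest camera adjusted p of these lists, in that order, were 0.584, 0.563, 0.528, 0.574, 0.0494, 0.528, 0.351, 0.358 and 0.528.

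Inflammation and cytokine genes (30 genes at 7 days) had a median sham level of 18.9% and median differences of −0.136 to 0.261 points. The 40 matrix and fibrosis genes had a sham median of 40.4%, and their median differences ran from −0.517 to 0.469 points. For 21 immune cell markers the sham median was 75.3% and the median difference −0.157 to 0.239 points. Endothelial and mural cell markers (23 genes at 7 days) had a median sham level of 59.0% and median differences of −0.0342 to 0.315 points. The 17 fibro-adipogenic and adipocyte markers had a sham median of 59.6%, and their median differences ran from −0.472 to 0.651 points. For 16 Schwann cell and nerve markers the sham median was 24.7% and the median difference −0.561 to 0.181 points. Genes of the DNA methylation machinery (27 genes at 7 days) had a median sham level of 26.0% and median differences of −0.0300 to 0.243 points. The 39 Hox genes had a sham median of 10.5%, and their median differences ran from −0.0915 to 0.240 points. For 33 imprinted genes the sham median was 53.6% and the median difference −0.404 to 0.229 points. Their smallest camera adjusted p, in that order, were 0.694, 0.574, 0.693, 0.351, 0.563, 0.528, 0.584, 0.351 and 0.528. Of the immune markers, 0 stood in another list, and expression in the muscle was not measured in these files. The atrophy list with boldine against sham at 28 days was the only one of 18 lists to pass camera in any of the 6 comparisons, and none passed with an estimated correlation or by fry.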

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

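The tests of depth and of an even loss in SCI vehicle replicate 2 of 28 days were chosen only after the result was seen, whereas the test on immune markers was not.

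SCI vehicle replicate 2 of 28 days had less methylation than the rest of its group at every level of methylation tested above 30%. Its mean was 38.0%, against 39.7 to 40.03% in the other 5 libraries. At CpGs whose mean level over the libraries of the day was 30 to 50% it had 36.1% (others 40.4 to 41.6%), at 50 to 70% it had 55.0% (60.7 to 61.7%), at 70 to 90% it had 77.4% (82.3 to 82.8%) and above 90% it had 93.1% (94.9 to 95.02%). Immune marker spans were lower too, with a median deviation of −5.41 points over 21 spans. Among those with larger falls, Itgax was at 66.0% against 75.9% ± 1.48 and Ms4a1 at 75.4% against 87.0% ± 3.29 (SD, n = 5). Myh7, a slow myosin gene, was at 66.2% against 82.4% ± 1.79 (SD, n = 5), in a contractile list with a median deviation of −1.49 points. The mean and the values of these 4 level classes each lay further from its neighbours than Dixon's test allows, which happens by chance in about 1 in 20 groups. In all 90 groups were tested and 7 such values found, 5 of them in this library.

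Low depth is argued against, since the library held 102.16 M calls (M stands for 10 to the power of 6) against 79.2 to 98.5 M in the others of its group. An even loss of methylated calls at every site is argued against as well, because 12.1% of methylation was missing at CpGs of 30 to 50% and 1.88% above 90%, a gap of 10.2 points with an SD of 1.47. A share of immune cells in the sample stays open and is a candidate explanation, since the 21 immune marker spans deviated by −5.41 points in median, against −2.80 in random lists matched on level, at percentile 0.12 of those lists. In a screen of the other lists added afterwards, Schwann cell and nerve markers stood at percentile 0.96 and contractile genes at 77.8. Endothelial and mural markers stood at 91.8 and fibro-adipogenic and adipocyte markers at 52.1. Schwann and nerve cells might thus contribute too, while the other cell type lists did not stand low. No group of the design separates this library from the rest of its group, so no biological explanation was tested other than the share of cell types.

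At the CpG near Gm29630, SCI vehicle replicate 5 of 28 days had 87.9%, against 77.5 to 81.3% in the others of its group. At the CpG in Zcchc24, sham replicate 1 of 7 days had 33.9%, against 44.4 to 46.2%. Mitochondrial calls per M calls of the library differed in their boldine effect between the days by 67.4 (exact permutation p = 0.0379), with 64.2 against 80.2 for boldine and SCI vehicle at 7 days and 149.7 against 98.2 at 28 days. This p is not adjusted for the number of library measures tested between the days, and no other of those tests had p under 0.05, so it can arise by chance.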

How the results depend on the processing

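The single prior dispersion, lane tag as a covariate for members of gene lists, the windows of 2000 bp and the shares at an unadjusted p under 0.001 were tests chosen only after the data had been seen. The cause was not tested for any change given here. Values in lists of 6 follow the order SCI vehicle against sham, boldine against SCI vehicle and boldine against sham, at 7 and then at 28 days.

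With a single prior for all features, 117, 115, 16, 168, 511 and 412 CpGs passed in place of 0, 0, 1, 1, 0 and 0, but simulated data gave 42.5 to 51.6% false calls with it. In fits of only the 2 groups compared, 3 CpGs passed for SCI vehicle against sham at 28 days, 1 for boldine against SCI vehicle and 7 for boldine against sham. Strands kept apart left 0 CpGs for boldine against sham at 7 days and 0 for SCI vehicle against sham at 28 days. With lane tag as a covariate, 0 CpGs passed for boldine against sham at 7 days, and for SCI vehicle against sham at 28 days 1 CpG passed, in Hdgfl3, in place of that in Prex1. Of list members with lane tag, calls ended for Sdhb, Acadm, Tgfb3, Myl2 and Irs2. Stim1 gained calls for boldine against SCI vehicle at both days, but with opposite signs, at −0.270 log odds at 7 and 0.349 at 28 days. Idh2 gained a call in the same comparison at 28 days (0.151 log odds). Stat3 gained calls at 28 days for SCI vehicle against sham (−0.172) and boldine against SCI vehicle (0.170). These 2 comparisons share the SCI vehicle libraries. A minimum of 5 reads gave 1 CpG for boldine against SCI vehicle and 1 window, in Ranbp3l, for SCI vehicle against sham, both at 28 days, and turned the mean difference of boldine and sham at 7 days to −0.00146 points. At 20 reads that of 28 days became 0.00802, Rcan1 turned to −1.61 points for boldine against SCI vehicle at 28 days and Bhlhe40 to 0.122 for boldine against sham. Pooled reads moved the mean differences to 0.502, 0.0252, 0.528, −0.686, 0.0833 and −0.602 points, which turned that of boldine and SCI vehicle at 7 days. edgeR gave 1 window for boldine against sham at 28 days. For that comparison, 0 lists passed with an estimated correlation, by fry or at 20 reads. Of windows with an unadjusted p under 0.001 at 28 days, 65.5% had the same sign at 7 days.

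Windows of same-number libraries correlated at −0.0501 to 0.0782. At 7 days libraries of other numbers gave the highest correlation in each comparison, but at 28 days those of the same number did. For SCI vehicle and sham at 28 days the ranges were −0.0178 to 0.0782 for the same and −0.0538 to 0.0362 for other numbers. All these correlations were small, and a pairing by replicate number at 28 days is neither shown nor excluded. As a replicate block, replicate numbers gave 9, 3, 1, 10, 1 and 0 CpGs, and 0 lists for boldine against sham at 28 days. Neighbouring CpGs were counted apart. The 9 lay in Gm43305 and near Zfp775, the 3 in Snd1, and the 10 near Zfp775, in Prex1 and in Hdgfl3. Near Zfp775 (chromosome 6, 48629345 to 48629618) these CpGs were lower in SCI vehicle than in sham at both days. Some of them also passed at 28 days in the fit of only the 2 groups compared, but none in the main test.

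Without each library in turn, mean differences ran over −0.0106 to 0.0708, −0.0981 to 0.0111, −0.0574 to 0.0517, −0.331 to 0.0743, −0.0771 to 0.327 and −0.0908 to 0.0602 points. Counts of CpGs ran over 0 to 1, 0 to 0, 0 to 3, 0 to 1, 0 to 1 and 0 to 1, and counts of windows over 0 to 1, 0 to 1, 0 to 2, 0 to 2, 0 to 1 and 0 to 0. Lists that passed ran over 0 to 0, 0 to 0, 0 to 0, 0 to 0, 0 to 0 and 0 to 1, and windows whose effect differed between the days over 0 to 0 for the injury and for boldine. A count of 0 in these ranges is by the quasi-binomial F test or camera. For named genes, 693 other planned values kept their state and direction, 9 lost a call, 3 gained a call and 2 turned. Without single libraries 2164 kept their state, 64 lost a call and 24 gained a call. Values that kept their state include features that passed neither before nor after, so these counts do not give the share of calls that held. The Prex1 call was lost for 7 of 10 libraries left out, that of 1700112J05Rik for 6 of 10 and that of Sdhb for 8 of 12, while Clock, Chrng, Tbx1 and Egr2 held each time.

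Not run were promoters of 2000 bp to each side, since the annotation has no strand. No window passed at either day, so the shares of windows in place of CpGs had no value, and no CpG passed for boldine against SCI vehicle, so its share at both days had none.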

Other observations

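The pooled comparison of injured with sham muscle, the shares of windows with the same sign at both days, the tests on nearly unmethylated CpGs and those on sequence variants, and the splits of gene lists were chosen only after the result was seen.

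Injured muscle of both days, with and without boldine, was pooled against sham, which gave 24 against 8 libraries. Besides the CpG in Prex1 (adjusted p = 2.53e-05), 2 further CpGs fell. One lies inside Zcchc24, a zinc finger gene (chromosome 14, 25749780 to 25749781), with 42.7% ± 5.90 (SD, n = 4) in sham, 28.9% ± 4.92 (SD, n = 6) in SCI vehicle and 32% ± 5.40 (SD, n = 6) in boldine libraries at 7 days and 44.0% ± 6.38 (SD, n = 4) in sham, 30.1% ± 6.71 (SD, n = 6) in SCI vehicle and 29.3% ± 5.72 (SD, n = 6) in boldine libraries at 28 days. The other lies 2612 bp outside Gm29630 (chromosome 1, 132265988 to 132265989), with 93.3% ± 5.43 (SD, n = 4) in sham, 79.2% ± 5.09 (SD, n = 6) in SCI vehicle and 83.8% ± 6.05 (SD, n = 6) in boldine libraries at 7 days and 91.9% ± 4.66 (SD, n = 4) in sham, 80.9% ± 3.64 (SD, n = 6) in SCI vehicle and 79.7% ± 8.30 (SD, n = 6) in boldine libraries at 28 days. Both had an adjusted p of 0.0332, and 9 of 12 injured libraries of 7 days lay below every sham library at either CpG, as did 12 at Zcchc24 and 9 at Gm29630 of 12 at 28 days. At Prex1 11 of 12 did so at 7 days and 12 of 12 at 28 days. Injured minus sham at the Gm29630 CpG was −11.8 points at 7 and −11.6 at 28 days. The covered CpG 6 bp further on differed by only −2.66 and 1.98 points, and that 22 bp on by −0.169 and −5.00. So the change near Gm29630 lay mainly at this 1 CpG. At the Zcchc24 CpG the values were −12.2 and −14.3 points, with −9.63 and −11.1 at the CpG 26 bp before it and −3.02 and −10.2 at that 11 bp on.

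Windows did not pass in the pooled test. The smallest p values belonged to Prex1, Mustn1, a gene of the muscle and skeleton, and Nup210, a nuclear pore gene needed in muscle differentiation. Injured minus sham was −6.73 points at 7 and −7.12 at 28 days in Mustn1 (chromosome 14, 30880001 to 30881000) and −6.26 and −7.84 in Nup210 (chromosome 6, 91014001 to 91015000), with an adjusted p of 0.101 each. The mechanosensitive channel gene Piezo1 had 8.93 and 8.84 points and Hoxc4 7.13 and 11. Within the atrophy list Klf15, a glucocorticoid target, and Map1lc3a, an autophagosome gene, were lower (adjusted p = 0.0287 each, adjusted over the list alone, and 0.880 over all), with differences of −1.15 and −0.950 points at Klf15 and −0.527 and −0.561 at Map1lc3a. In all, 3 CpGs, 0 windows and 0 gene spans passed the F test, with 55278, 4703 and 1081 at an unadjusted p under 0.05. Pooled without SCI vehicle replicate 2 of 28 days, 5 CpGs passed, with Eef1a2 and C2cd4b added, and without boldine replicate 6 of 28 days 4, with Zfp560 added. At 28 days alone Ranbp3l passed as a window, at −12.7 points and an adjusted p of 0.0321, next to −1.99 points at 7 days. With SCI vehicle or boldine libraries alone set against sham over both days, only the Prex1 CpG passed the F test (adjusted p = 0.00119 and 0.000680). The calls at Zcchc24 and Gm29630 thus appeared only with both injured groups together.

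The 3 CpGs were weighed against technical explanations. A sequence variant that removes the CpG is argued against at Prex1 and Gm29630, where 0 of 24 injured values (0%) lay near 0 or near 50% of the sham level, but cannot be told apart at Zcchc24, where 20.8% did. Sequencing lane is argued against as the whole cause, as the lowest ratio of the difference within a shared lane tag to the whole difference was 0.775, although the Prex1 call at 28 days ended with lane as a covariate, where the effect went from −1.20 ± 0.209 to −1.23 ± 0.232 log odds (standard error). Immune cells that entered injured muscle would place immune marker spans lower than random lists matched on level. The median injured minus sham difference of these spans was instead higher, at 0.311 points against 0.194 in matched lists at 7 days. At 28 days it was 0.0133 against −0.255. These medians stood at percentiles 64.0 and 83.5 of the matched lists, inside their spread. They thus do not point to immune cells, but do not exclude them either. An effect of the injury on these sites stays open as well, and 3 of 40 splits of the pooled libraries gave as many CpGs as the real 3, the highest other 20, so that chance is not excluded.

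Boldine libraries had less methylation than SCI vehicle libraries at nearly unmethylated CpGs. At CpGs under 2% the mean was 0.770% ± 0.0161 with boldine and 0.818% ± 0.0125 with vehicle (SD, n = 6) at 7 days, a difference of −0.0484 points (exact permutation p = 0.00216; 0.130 adjusted over 60 tests), and −0.0296 points at 28 days (exact p = 0.0130; 0.260 adjusted), while boldine minus sham was −0.0609 (exact p = 0.00952; 0.260 adjusted) and −0.0123 points (exact p = 0.438), so that none passed after adjustment. Sequencing lane is argued against, as within lane tag 2 the difference was −0.0402 points (exact p = 0.00952). Fewer unconverted cytosines cannot be told apart, since the gap between the differences at CpGs of 2 to 10% and at those under 2% was −0.178 points with a standard error of 0.105, and mitochondrial methylation, a further measure of unconverted cytosines, was also lower, with differences of −0.300 points from SCI vehicle at 7 days (exact p = 0.0952; 0.698 adjusted over 60 tests), −0.351 at 28 days (exact p = 0.0303; 0.364 adjusted) and −0.242 from sham at 28 days (exact p = 0.0190; 0.286 adjusted). A lasting effect of boldine is a candidate explanation that stays open, the change between the days having an exact p of 0.378.

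Groups were also split at random, with 100 splits per comparison, the real one included. Where the real count was 0, every split gives as many by necessity, so that share tests nothing. In those cases only the highest other count is informative. For CpG counts of 0, 0, 1, 1, 0 and 0 for SCI vehicle against sham, boldine against SCI vehicle and boldine against sham at 7 and then 28 days, 100, 100, 20, 28, 100 and 100 of 100 splits gave as many, and the highest others were 6, 13, 13, 34, 5 and 41. For windows the real counts were 0 and 100 of 100 splits gave as many each time, with highest others of 4, 3, 13, 4, 3 and 2. For list genes adjusted over the list alone, with real counts of 1, 2, 5, 3, 4 and 1, the numbers were 60, 25, 10, 25, 5 and 57 of 100 splits, with highest others of 10, 49, 22, 13, 6 and 5. For lists, 100 of 100 splits gave as many as the real 0 in 5 comparisons, with highest others of 1, 1, 2, 3 and 1. For boldine against sham at 28 days 3 of 100 splits gave as many as the real 1, with a highest other of 1. For effects that differ between days, 50 of 50 splits gave as many as the real 0, with highest others of 2 and 1. That single list count alone was reached by fewer than 1 in 20 splits. Several counts above 0 were compared, however, and 1 such outcome among them can arise by chance. Chance is therefore not firmly excluded for the list, and it is not excluded for the calls of Prex1, Clock and Chrng. The list call also ended with an estimated correlation (adjusted p = 0.447) and by fry (0.293, with 0.0494 by camera). Splits with many calls, several times the real count, point to a structure of the samples, the nature of which was not tested.

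Windows with an unadjusted p under 0.001 for SCI vehicle against sham at 28 days, 113 in number, had the same sign at 7 days in 65.5% of cases. Of 100 splits of the 7-day libraries 2 gave a share as large, and the highest other was 69.0%. This is under 1 in 20, but the share was picked among several after they had been seen, so chance is not firmly excluded. Chosen at 7 days instead, 56.3% of 71 windows had the same sign at 28 days, and 16 of 100 splits gave as large a share. For CpGs the shares were 51.2% and 50.7%, with 31 and 24 of 100 splits as large. Other comparisons of windows went both ways. For boldine against SCI vehicle the share was 41.3% of 63 windows chosen at 28 days and 62.0% of 108 chosen at 7 days. For all injured against sham it was 65.4% of 81 and 43.2% of 95, with 3 and 92 of 100 splits as large.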
